A study of Homo sapiens with 22 samples.

How the data were processed

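Chromatin immunoprecipitation with sequencing was compared between wild-type HEK293 cells, a human embryonic kidney line, and HEK293 cells in which pyruvate kinase M (PKM) was depleted by a stably expressed short hairpin RNA delivered by lentivirus. Per the labels, human chromatin was mixed with a small amount of Drosophila S2 cell chromatin before the immunoprecipitation (ChIP-Rx). Such foreign chromatin can serve as a common scale between libraries. There were 4 antibodies (against H3K4me3, H3K9ac, MondoA and MLX) with 2 libraries per cell type and antibody, which gave 16 libraries with a peak list. Per the labels, the histone-mark libraries formed batch 1 and the transcription factor libraries batch 2, so every comparison of cells lay within a batch. The 6 input libraries were not used here. No sample is labelled as carrying a control hairpin or an empty vector. A difference between the cells may therefore come from the vector, from the hairpin or from the loss of PKM, which the design cannot separate. Nothing in the labels says that replicates came from separate cultures. The p-values of limma and of the permutation tests of peak numbers therefore measure only the spread between these libraries, which may be technical. Those of Fisher's exact test and of comparisons with random sets of regions count genes or regions and hold no spread between libraries.

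The submitters' processing notes name cutadapt 3.4, Bowtie2 2.4.4, MACS2 2.2.7.1 and deepTools 3.5.1, with the builds hg38 and dm6. The settings, the control library of each peak list and the use of the spike-in reads are not given in the sources used here. The authors deposited one list of narrow peaks per library, so replicates had not been pooled. The peak positions and summits in the deposited lists were in base pairs on hg38. The deposited fold enrichment of each peak (a ratio of the summit over the local background) is the authors' value. It was used to describe and rank peaks and, with the p-value, to recover a pileup and a local background. The deposited lists also gave the −log10 of the p and q values, and the authors' score was that −log10 q on a scale of whole numbers. The peaks lay on chromosomes 1 to 22 and X. The histone-mark and MondoA lists ended at a −log10 q of 3.00 to 3.30. The MLX lists ended at 9.55 and 4.89 in knockdown replicates 1 and 2 and at 10.6 and 9.36 in wild type. No value in the lists showed scaling to the spike-in, so no statement about the total amount of a mark per cell could be made.

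The lists hold no read counts. The fold and p-value of each peak were therefore solved together for a fragment pileup and a local background. The pileup came out whole, within a tolerance of 0.001 on the −log10 p scale, for 98.3% to 100% of the peaks in each list for the histone marks and MondoA, and for 87.0% to 91.9% of those for MLX. After the folds were altered on purpose, 0% to 0.155% came out whole. The lowest background in each list, which scales with the number of fragments and their length, was used as a measure of relative depth. It was 1.62 to 1.77 fragments for H3K4me3, 1.41 to 1.97 for H3K9ac, 1.87 to 2.31 for MondoA and 1.52 to 2.88 for MLX. Total read numbers were not used here.

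Peaks of the 4 lists of an antibody were merged into regions when they shared at least 1 bp. A region was called only in knockdown, or only in wild type, when both lists of those cells and neither list of the other cells had a peak there. The same counts for the 2 splits that mix the cells were set beside these. A region counts there only if, in both cell types, 1 replicate called it and the other missed it. Such counts can therefore fall below replicate noise. For H3K4me3, 422 and 431 regions were called in a single knockdown list and 52 and 58 in a single wild-type list. Numbers of peaks were compared by an exact two-sided permutation test, whose smallest possible p with 2 libraries per group is 0.333. For regions called in all 4 lists, the base pairs covered by peaks were put on the log2 scale, centred on the median of each library and tested with limma (trend and robust settings). Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The presence counts were tested on 20 simulated sets of peaks, and 100% equalled a count made base by base. In simulated H3K4me3 data with 200 of 15109 regions changed, the length test recovered 0% of changes of 0.25 or 0.5 on the log2 scale, 93% of those of 1 and 99% of those of 2. In simulated H3K9ac data with 200 of 14273 regions changed it recovered 0% of changes of 0.25, 0.5 or 1 and 93.5% of those of 2. The real H3K4me3 calls included changes as small as 0.36 for longer and 0.37 for shorter regions. The simulated shares are therefore only a rough measure of what the test can find in these data.

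Gene positions came from a RefSeq table of GRCh38, the assembly that hg38 names. The table gave no strand, so a peak was assigned to a gene when it lay within 1 kb of either annotated end of a protein-coding gene, in place of a transcription start site. This rule also takes in peaks at the far end of a gene. All 302 distinct members of 16 gene lists were found among 19974 protein-coding genes. The lists were MondoA and MLX targets, the arrestin domain family, glycolysis and lactate, the pentose phosphate pathway, serine and one-carbon synthesis, the tricarboxylic acid cycle and pyruvate entry, lipid synthesis, the amino acid and endoplasmic reticulum stress response, the hypoxia response, the MYC, MAX and MLX network, the oxidative stress response, histone acetylation enzymes, ribosomal proteins, and markers of kidney, of neural and adrenal, and of liver, blood and muscle cells. Gains and losses of peaks in each list were tested with Fisher's exact test, two-sided, in a family of 64 tests, with genes that had a peak of that mark as background. MondoA regions called in both libraries of at least 1 cell type were compared with 1000 random placements on the same chromosomes. A search for the E-box motif under MondoA summits needs the genome sequence and was not made here.

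The groups, tests, gene lists and alternatives were chosen before the data were examined, except where stated. The named items were PKM, TXNIP and ARRDC4 for every antibody, and, for each antibody, the 10 regions called only in knockdown and the 10 called only in wild type with the highest fold in the weaker of their lists. For MondoA and MLX, the rule added the 10 strongest regions called in all 4 lists. It also took the 10 largest changes of length in each direction, the gene list members gained or lost, and up to 4 other members per list. List members that passed only adjusted over the list alone, other list members bound by MondoA, genes that gained both marks and the site near POLR3GL were named after their values were seen. Some items that the rule would name are not reported here. A region was named by a gene end within 10 kb and otherwise by its position. The alternatives were a −log10 q of at least 5, the same number of peaks per list, 50% of a region covered, a window of 2.5 kb, another background, no centring, an added constant before the log2 scale, a replicate block and each library left out in turn. Intervals for shares are Wilson intervals at 95% and cover counting error only. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.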

Results

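The 16 peak lists covered H3K4me3 and H3K9ac, histone marks found at active promoters, and MondoA and MLX, transcription factors that bind DNA as a pair and respond to glucose-derived metabolites. Each antibody had 2 libraries from wild-type HEK293 cells and 2 from HEK293 cells with stable knockdown of PKM, which encodes the enzyme of the last step of glycolysis. The lists held 15606 to 17013 peaks for H3K4me3, 15281 to 19608 for H3K9ac, 645 to 1082 for MondoA and 23 to 62 for MLX. The median summit pileup was 142 to 180 fragments for H3K4me3, 52 to 69 for H3K9ac, 23 to 25 for MondoA and 35 to 58.5 for MLX. Of the H3K4me3 peaks, 97.0% to 97.5% overlapped a peak of the other replicate of the same cells. That share was 88.9% to 95.2% for H3K9ac, 50.1% to 75.5% for MondoA and 54.8% to 97.1% for MLX. The series title concerns a link between pyruvate kinase and TXNIP. The comparisons asked how these marks and factor binding differed between knockdown and wild-type cells, with TXNIP among the genes named in every list.

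At PKM itself (chromosome 15, 72199029 to 72231591, hg38), one H3K4me3 peak lay at a gene end in all 4 libraries. It covered 4534 and 4366 bp in knockdown and 4477 and 4390 bp in wild type (4450 ± 119 against 4434 ± 61.5 bp, SD, n = 2), a centred log2 change of −0.05 (SE 0.043, limma adjusted p = 0.608). The H3K9ac peak at PKM covered 6177 and 5383 bp in knockdown and 4898 and 4704 bp in wild type (log2 change 0.04 relative to the shift of 0.22 in the library medians of H3K9ac, limma adjusted p = 0.891). No MondoA or MLX peak lay within 1 kb of an end of PKM in any of the lists. A short hairpin RNA acts on the transcript, so a promoter mark does not check the knockdown.

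TXNIP, which encodes a protein that binds thioredoxin and restrains glucose uptake, had a longer H3K4me3 region after PKM knockdown. The region spanned 145994226 to 145997400 on chromosome 1, at one end of the gene (145992435 to 145996579). The peak covered 3148 and 3172 bp in knockdown and 1950 and 1857 bp in wild type (3160 ± 17.0 against 1904 ± 65.8 bp, SD, n = 2), a ratio of 1.66. The centred log2 change was 0.68 (SE 0.054, limma adjusted p = 0.0378) and most of the added length lay on the side of the gene body. With a replicate block, limma called 0 H3K4me3 regions, TXNIP included (lowest limma adjusted p 0.071). The H3K9ac peak there covered 3298 and 3182 bp in knockdown against 1814 and 1558 bp in wild type, a ratio of 1.92 and a log2 change of 0.73 beyond that shift (SE 0.106), which did not pass over all regions (limma adjusted p = 0.269). The authors' fold at the H3K4me3 peak was 62.2 and 63.8 in knockdown and 31.0 and 36.3 in wild type, and that at the H3K9ac peak was 30.2 and 30.4 against 14.1 and 16.8. ARRDC4, the arrestin domain paralogue of TXNIP, had H3K4me3 peaks of 2397 and 2531 bp in knockdown and 2054 and 2180 bp in wild type (log2 change 0.17, SE 0.059, limma adjusted p = 0.304). Its H3K9ac peaks covered 2270 and 2371 bp against 2046 and 1026 bp (log2 change 0.46, SE 0.298, limma adjusted p = 0.599). The authors' fold rose at ARRDC4 as well. It was 106.6 and 107.7 in knockdown and 57.35 and 56.83 in wild type for H3K4me3, and 34.03 and 36.99 against 18.61 and 16.93 for H3K9ac. Without knockdown replicate 1, and without knockdown replicate 2, limma called 0 H3K4me3 regions of changed length, TXNIP included.

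**Figure D1:**
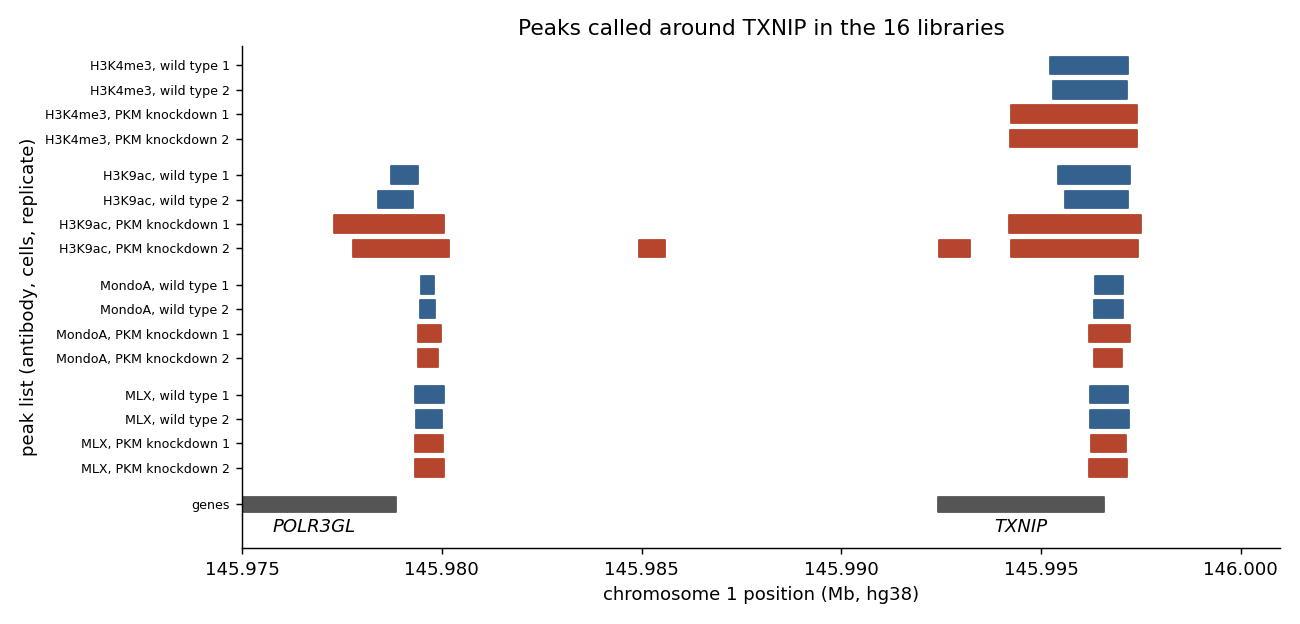
Peaks of the 16 lists along chromosome 1 (position in Mb, hg38) around TXNIP, one row per library, with wild type in blue, PKM knockdown in red and the spans of POLR3GL and TXNIP in gray. The H3K4me3 peak at TXNIP covered 3148 and 3172 bp in knockdown and 1950 and 1857 bp in wild type, and MondoA and MLX peaks lay at both sites in every list.

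A region close to POLR3GL, a subunit gene of RNA polymerase III that is the neighbour of TXNIP, was singled out after its values were seen. Its H3K9ac peak (chromosome 1, 145977312 to 145980187) covered 2753 and 2412 bp in knockdown and 679 and 874 bp in wild type (2583 ± 241 against 777 ± 138 bp, SD, n = 2), a ratio of 3.33. The log2 change beyond that shift was 1.52 (SE 0.196), and 0.0631% of H3K9ac regions gained as much, but it did not pass over all regions (limma adjusted p = 0.255). MondoA and MLX peaks lay there in all 8 lists, with an authors' MLX fold of 159 and 326 in knockdown and 141 and 132 in wild type. The MLX fold was also higher in knockdown replicate 2 than in replicate 1 at TXNIP (1882 against 912) and ARRDC4 (1643 against 822), though not at DHRS2 (36.5 against 40.6). The value of 326 therefore does not single out this site.

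H3K4me3 was called at more places in knockdown cells. The knockdown lists held 16994 and 17013 peaks and the wild-type lists 15606 and 15648 (17004 ± 13.4 against 15627 ± 29.7, SD, n = 2), a ratio of 1.09 ± 0.00224. The groups were separated by many times the spread between replicates, and the exact permutation p of 0.333 was the smallest that 2 against 2 libraries allow. Of 17594 merged regions, 781 were called only in knockdown and 15 only in wild type, while the mixed splits gave 24 and 31, and 35 and 29. Leaving out a knockdown library, replicate 1 or 2, raised the first count to 1212 or 1203, and leaving out any library raised the second, to 27 or 34 for the knockdown and 73 or 67 for the wild-type replicates. The strongest of the 781 lay 4971 bp from CALY, which encodes a neuronal membrane protein, inside ZNF511-PRAP1 (chromosome 10, 133318503 to 133319101), with authors' folds of 30.2 and 28.6. Others lay at an end of SPEF1, a gene of the sperm flagellum and cilia (chromosome 20, 3780936 to 3781535, folds 19.1 and 20.7), inside EMC3, a subunit gene of the membrane protein complex of the endoplasmic reticulum (chromosome 3, 10008686 to 10009291, folds 21.3 and 19.7), and near TEX261, ZNF518A and MRTFA. The strongest wild-type regions lay inside DCLRE1A, a DNA crosslink repair gene (chromosome 10, 113851214 to 113852048, folds 8.54 and 8.86), inside HDAC5 (folds 8.47 and 7.68) and inside MYH9 (folds 6.94 and 7.49). TLR3, CELSR1 and DOK4 also had such regions. Only 153 (19.6%) of the 781 lay within 1 kb of a gene end, against 10968 (72.6%) of the 15109 regions called in all lists, and their median width was 626 against 1949 bp. The median authors' fold was 50.9 ± 0.273 in the knockdown lists and 41.9 ± 0.436 in the wild-type lists (SD, n = 2). When every list was held to the same number of peaks, 226 regions were called only in knockdown and 174 only in wild type.

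**Figure D2:**
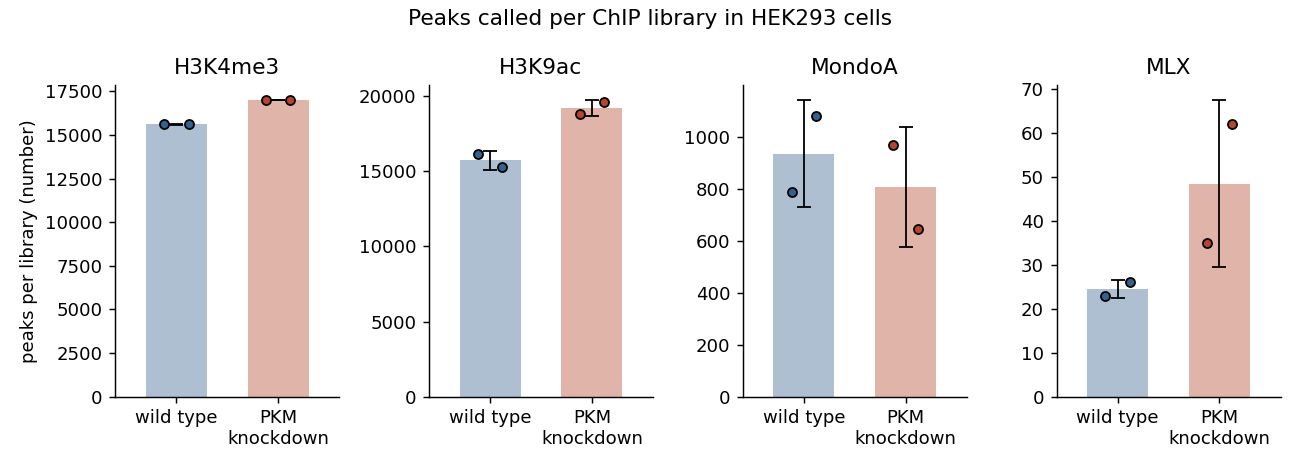
Number of peaks per library for each antibody, with bars for the mean of 2 libraries, error bars for the SD and points for single libraries. The H3K4me3 and H3K9ac knockdown libraries all lie above the wild-type libraries, while the MondoA libraries of the cells overlap.

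In the 15109 H3K4me3 regions called in all lists, 29 were longer and 13 shorter in knockdown by limma, and without centring on the library medians the split was 37 and 8. With a replicate block limma called 0 (lowest limma adjusted p 0.071). Among the longest gains were the end of POU4F2, a transcription factor of retinal ganglion cells (chromosome 4, 146637092 to 146639508), with 2343 ± 36.1 bp in knockdown and 1055 ± 47.4 bp in wild type (SD, n = 2; log2 change 1.1, SE 0.066, adjusted p = 0.0229). SLITRK3, a synaptic adhesion gene, had 1522 ± 178 against 549 ± 18.4 bp (log2 change 1.41, SE 0.118, adjusted p = 0.0378). GLRX, which encodes glutaredoxin, had 2600 ± 9.9 against 1321 ± 122 bp (log2 change 0.93, SE 0.075, adjusted p = 0.0378). Among the called regions, the largest gains lay inside SPATA13 (chromosome 13, 24270523 to 24272468, log2 change 1.66) and inside OLFM1 (chromosome 9, 135086241 to 135088448, log2 change 1.63), and TMEM185B, EML2, ANKRD53 and sites on chromosomes 12 and 3 completed the 10. The loss at BTBD19 (chromosome 1, 44807550 to 44809078) was from 1313 ± 29.7 bp in wild type to 570 ± 61.5 bp in knockdown (log2 change −1.26, SE 0.117, adjusted p = 0.0378). NBEAL1 fell by 0.89 and UBA1, which encodes the ubiquitin-activating enzyme, fell by 0.60 on the log2 scale. The ribosomal protein genes RPL7 and RPS24 fell by 0.63 and 0.54, and RABL6, TIAL1, S100A10 and a site on chromosome 21 were also among the 10 largest losses. S100A10 and the chromosome 21 site did not pass without centring (limma adjusted p = 0.0578 for each). The mixed splits of the libraries gave 0 calls each. Each mixed group held both cell types, so a difference between the cells widened the spread within groups, and these 0 calls do not measure replicate noise. In the comparison of the cells, 2221 regions had an unadjusted limma p under 0.05. Without knockdown replicate 1 or knockdown replicate 2 limma called 0, while it called 104 without wild-type replicate 1 and 165 without wild-type replicate 2.

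**Figure D3:**
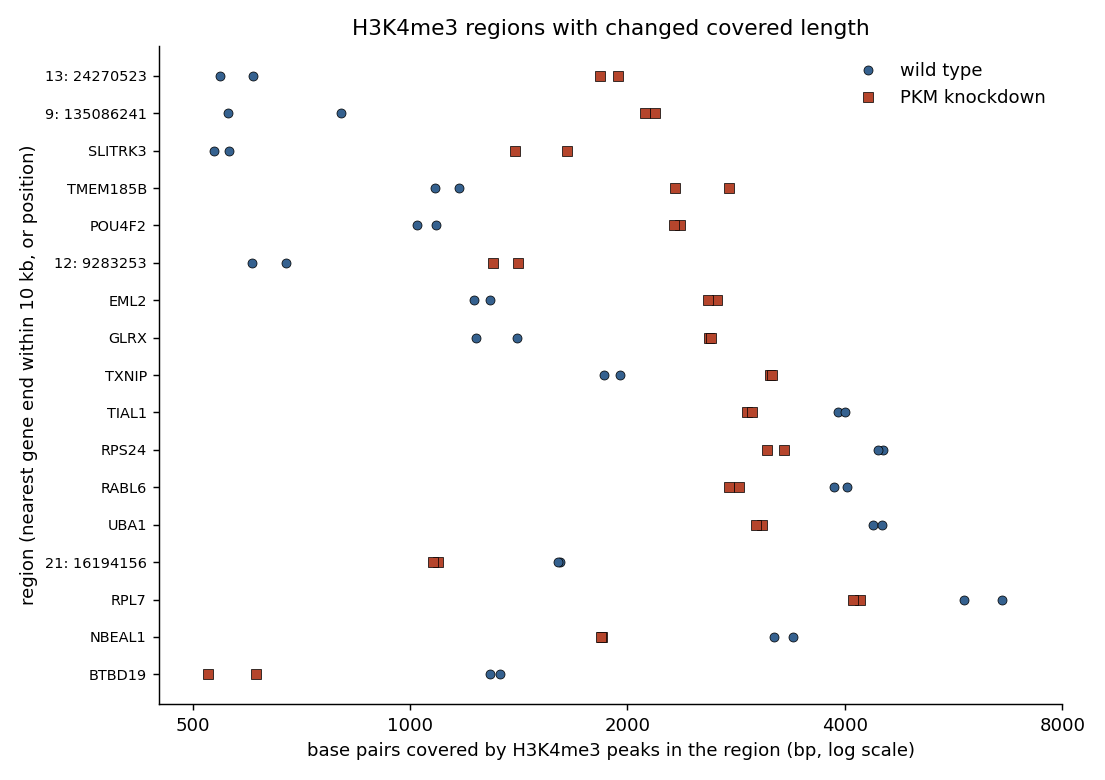
Base pairs covered by H3K4me3 peaks (log2-scaled axis) in 17 regions, the 8 largest gains and the 8 largest losses among called regions and TXNIP, with circles for wild-type and squares for knockdown libraries. At POU4F2 the knockdown libraries covered 2368 and 2317 bp and the wild-type libraries 1088 and 1021 bp.

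H3K9ac was also called at more places in knockdown cells. The knockdown lists held 18842 and 19608 peaks and the wild-type lists 16167 and 15281 (19225 ± 542 against 15724 ± 626, SD, n = 2), a ratio of 1.22 ± 0.0597 with the smallest possible exact p of 0.333. Of 21344 merged regions, 1660 were called only in knockdown and 33 only in wild type, against 98 and 75, and 67 and 199, in the mixed splits. The first count rose to 3488 without knockdown replicate 1, 2818 without knockdown replicate 2 and 2661 without wild-type replicate 1. The second rose to 77 or 85 without knockdown replicate 1 or 2, and to 177 or 335 without wild-type replicate 1 or 2. The strongest knockdown region lay inside PRRC2A, 222 bp from a gene end (chromosome 6, 31620937 to 31621430, folds 33.8 and 32.0). Others lay at an end of TESMIN, a testis-expressed gene (chromosome 11, 68751102 to 68752056, folds 20.8 and 21.8), 6320 bp from ATF3, a stress-induced transcription factor (chromosome 1, 212558556 to 212559087, folds 16.1 and 20.2), and near HES6, THBS2 and CALY, the last at the place where H3K4me3 also appeared. Wild-type regions lay near RASD2 (folds 7.75 and 7.53), ZNF341 (folds 6.61 and 5.11), SGCA (folds 5.10 and 5.44) and TLX1 (folds 4.73 and 4.82). Of the 1660 regions, 294 (17.7%) lay within 1 kb of a gene end, against 10487 (73.5%) of the 14273 called in all lists. In these 14273 regions limma called 0 of changed length relative to the median shift, with 1491 at an unadjusted p under 0.05 and a lowest adjusted p of 0.255. With the same number of peaks in each list, 373 regions were called only in knockdown and 263 only in wild type.

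The gained marks met at some genes. Of the 270 genes with an H3K9ac peak only in knockdown, 20 (7.41%) also had an H3K4me3 peak only in knockdown, against 1.04% of the other genes with a peak of either mark (odds ratio 7.61, Fisher's exact test, two-sided, p = 4.73e-11). That background held many of the 12507 genes with H3K4me3 in every list, which could not gain it, so other backgrounds were tried after seeing the data. Among 7104 genes without a wild-type peak of either mark, 21.3% of those that gained H3K9ac gained H3K4me3, against 1.38% of the rest (odds ratio 19.3, Fisher's exact test, p = 2.02e-17). Among the 378 of these with a peak of either mark in knockdown it was 21.3% against 34.2% (odds ratio 0.521, Fisher's exact test, p = 0.0206), so the direction of the test turned with the background. Of the 20 genes, those named here were chosen after their values were seen, and they included the adjacent STAT5A and STAT5B, which encode cytokine signalling transcription factors, and IL11RA, a cytokine receptor gene. CYP3A5, a drug-metabolising enzyme gene, HOXB3, IKZF3, IFIT2 and ACTC1, the cardiac actin gene, were also among them. Across all regions, 172 were called only in knockdown for both marks, which was 22% of the H3K4me3 set and 10.4% of the H3K9ac set.

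No gene of the metabolic lists gained or lost a histone peak in both libraries of its cells. Most members with a peak already had it in every list, which left little room for a gain. For H3K4me3 this held for all 27 genes of the tricarboxylic acid list and 19 of the 20 glycolysis genes with a peak. Losses numbered 1 gene for H3K4me3 and 2 for H3K9ac among all genes, so the tests of loss could hardly pass. In the 64 tests of gained or lost peaks, 0 lists passed (Fisher's exact test, 1 at an unadjusted p under 0.05, lowest adjusted p 0.265). That 1 was the liver, blood and muscle list, in which APOA1, an apolipoprotein gene, and CD3E, a T cell receptor subunit gene, had H3K9ac only in knockdown (2 of 5 members with a peak, 40%, against 2.07% of other genes). Without wild-type replicate 1 the list passed, with 4 of 5 members (adjusted p = 0.000843). The only other members gained were EYA1 for H3K9ac in the kidney list and INA for H3K4me3 in the neural and adrenal list. No member of any list lost a histone peak.

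Length changes in the lists were few. Of 16 H3K4me3 regions at MondoA and MLX targets, limma called 1 longer over all regions, TXNIP, and 4 adjusted over the list alone. These were TXNIP and GPD1 (log2 change 0.36), which encodes glycerol-3-phosphate dehydrogenase, as longer, and BHLHE40 (−0.27) and RGS16 (−0.35) as shorter. Another region 9865 bp from RGS16 (chromosome 1, 182614254 to 182616460) was longer over all regions (log2 change 0.64, limma adjusted p = 0.0471). For H3K9ac at the same targets the count was 0 over all regions and 2 adjusted over the list alone, TXNIP and GPD1, the latter with 3568 and 3446 bp in knockdown and 1515 and 1646 bp in wild type. TXNIP was also the 1 call in the arrestin list of 5 H3K4me3 regions, with 1 adjusted over the list alone for each mark. Of 38 H3K4me3 regions at genes of the fixed ribosomal protein list, which does not hold RPS24, 1 was shorter over all regions, RPL7, and 10 were shorter adjusted over the list alone, among them RPL4 (−0.28) and RPL12 (−0.17). Of 16 at lipid synthesis genes 0 passed over all regions and 5 adjusted over the list alone, 4 shorter, among them SCD (−0.33), SQLE (−0.18) and SREBF2 (−0.19), and 1 longer, ACACB (0.40). In the serine list 0 of 11 passed over all regions and 2 adjusted over the list alone, PSPH (−0.44) and SLC1A5 (−0.17), both shorter. In the stress response list 0 of 17 and 2 passed likewise, ASNS (0.44) and DDIT3 (0.22), both longer. The oxidative stress list had 0 of 14 and 1 adjusted over the list alone, GCLC (0.35), and the kidney list 0 of 5 and 1, LRP2 (0.44), both longer. MYOD1, the muscle regulator, was longer over all regions (0.59) and was the 1 call of its list of 3 regions in each count.

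For H3K4me3, limma called 0 regions, over all regions and adjusted over the list alone, in the glycolysis list (21 regions, 2 at an unadjusted p under 0.05), the pentose phosphate list (9 and 1), the tricarboxylic acid list (27 and 3), the hypoxia list (14 and 1) and the MYC, MAX and MLX list (19 and 4). The same held for the histone acetylation enzymes (26 and 1) and the neural and adrenal markers (10 and 1). At LDHA, which encodes a lactate dehydrogenase subunit, the log2 change was 0.01 (limma adjusted p = 0.926), and at HK2, a hexokinase gene, it was −0.12. For H3K9ac, limma called 0 regions in every list over all regions and 0 adjusted over the list alone in the 14 lists other than the MondoA and MLX targets and the arrestin family, with 0 to 5 per list at an unadjusted p under 0.05.

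ARRDC4 and TXNIP held the top 2 ranks by authors' fold in 3 of the 4 MondoA lists, and ranks 2 and 3 behind PGK1 in knockdown replicate 2. At ARRDC4 (chromosome 15, 97960103 to 97961210) the authors' fold was 225 and 190 in knockdown and 109 and 106 in wild type, and at TXNIP (chromosome 1, 145996196 to 145997239) it was 206 and 158 against 102 and 107. DENR, a translation reinitiation factor gene, had folds of 37.8 and 36.5 against 44.2 and 38.2, and ZFX, ERCC6L2, INO80D, RBM39 and BTBD10 were also among the 10 strongest regions called in all lists. PGK1, a glycolytic gene, had folds of 91.3 and 366 against 29.0 and 25.1, at a site whose mean local background over the floor was 12.6 in the wild-type and 2.13 in the knockdown lists of both factors. Per the labels the second batch had 1 input per cell type, so these lists may share a control and no spread is given. The number of MondoA peaks, 970 and 645 in knockdown and 789 and 1082 in wild type, overlapped between the cells (808 ± 230 against 936 ± 207, SD, n = 2; ratio 0.863 ± 0.311; exact permutation p = 0.667). The ratio turned to 1.04 without knockdown replicate 2 and to 1.02 without wild-type replicate 2. Of 1636 merged regions 357 were called in all lists, 37 only in knockdown and 102 only in wild type. The mixed splits gave 47 and 31, and 115 and 13, so neither set stood out from them. Without knockdown replicate 1 or 2 the count only in knockdown was 121 or 267, and without wild-type replicate 1 or 2 it was 59 or 106. The count only in wild type was 193 without knockdown replicate 1 and 387 or 226 without wild-type replicate 1 or 2.

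Among the knockdown MondoA regions, the strongest lay 361 bp from an end of MPC2, a subunit gene of the mitochondrial pyruvate carrier (chromosome 1, 167936353 to 167936711, folds 7.60 and 8.08). SSR1 (folds 9.06 and 7.08), KAZALD1 (7.15 and 7.63) and PDRG1 (7.51 and 6.66) were also among the 10 strongest. Among the wild-type regions were ZBTB7A, a transcriptional repressor gene (folds 7.72 and 9.53), RPS15A (8.35 and 7.67), CENPB, a centromere protein gene (7.54 and 8.12), CCDC121 (7.84 and 8.02) and GABPB1 (6.96 and 8.95). Among list members, MPC2 and SIRT1 had MondoA only in knockdown and KAT2A and RPS23 only in wild type. In all lists, MondoA was called, among others, at TXNIP, ARRDC4 and KLF11 of the 20 targets, at PFKM and PGK1 in the glycolysis list, at MDH2 in the tricarboxylic acid list, and at 9 of the 40 ribosomal protein genes. At PGK1, plasmid reads are a candidate explanation, as given in the last section.

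MLX was strongest at the same genes. TXNIP (chromosome 1, 145996193 to 145997194) held rank 1 in all 4 MLX lists with folds of 912 and 1882 in knockdown and 1095 and 1165 in wild type, and ARRDC4 (chromosome 15, 97960018 to 97961016) held rank 2 with folds of 822 and 1643 against 864 and 890. The site near POLR3GL and KLF11, a Krüppel-like transcription factor gene, held ranks 3 and 4 in either order, with folds at KLF11 of 153 and 321 against 124 and 139. PGK1, with the same doubt about plasmid reads, and the end of KLF10, a gene related to KLF11, were also among the 10 strongest. The end of KLF10 had 64.4 and 117 against 35.7 and 42.9. A site inside PFKFB3, which encodes an enzyme that makes a regulator of glycolysis, had 70.5 and 131 against 48.3 and 54.0 (chromosome 10, 6163475 to 6164103). The MLX lists held 35 and 62 peaks in knockdown and 23 and 26 in wild type (48.5 ± 19.1 against 24.5 ± 2.12, SD, n = 2; ratio 1.98 ± 0.798; exact permutation p = 0.333, the smallest possible). The weakest peak had a −log10 q of 4.89 in knockdown replicate 2 and of 9.36 to 10.6 in the other lists, so the lists ended at unlike strengths. Of 63 merged regions, 21 were called in all lists, 8 only in knockdown and 0 only in wild type, with 0 in each mixed split. No region was called in wild-type replicate 1 or 2 alone, so a mixed split could hardly hold one. The 8 lay at PRRC2C (folds 8.82 and 16), at PDHB, a pyruvate dehydrogenase subunit gene (chromosome 3, 58433857 to 58434219, folds 8.67 and 18.3), at HES1, a Notch-responsive repressor gene (chromosome 3, 194135887 to 194136241, folds 6.55 and 17.9), at SIL1, near MORN1, inside PKP1, inside TUB and at a site on chromosome 9. The same number of peaks per list left 1 region only in knockdown and 2 only in wild type. Without knockdown replicate 1 the count only in knockdown was 35, and without knockdown replicate 2 the count only in wild type was 1.

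MondoA lay almost entirely in marked chromatin. Of 707 MondoA regions, 698 (98.7%, 95% Wilson interval 97.6% to 99.3%) overlapped an H3K4me3 region and 701 (99.2%, 98.2% to 99.6%) an H3K9ac region of the same cells, against means of 1.70% and 1.97% over 1000 random placements. An MLX peak lay in 18 (2.55%, 1.62% to 3.99%) of the 707, among them those at TXNIP, ARRDC4, KLF10, KLF11 and PFKFB3, compared with 0.291% of 16512 H3K4me3 regions. The MLX lists merged to 63 regions in all, so few of the 707 could hold one. The share therefore does not measure how often MondoA lay without MLX. In the other direction, 15 (71.4%) of the 21 MLX regions called in all lists held a MondoA region, and 0 of the 8 called only in knockdown did. Of the 722 genes with MondoA at an end, 0 gained H3K9ac against 2.21% of the other genes with an H3K9ac peak (Fisher's exact test, two-sided, p = 2.78e-07), and 721 of the 722 already had H3K9ac in every list, which left almost no room for a gain. None of the 722 lost it.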

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

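Leaving out 1 library, with the lone library of an arm assumed to vary like the other arm, gave these ranges. H3K4me3 regions only in knockdown numbered 1056 to 1212 (over 1.5 times the full count without either knockdown library) and those only in wild type 27 to 73 (every library). H3K9ac gave 2070 to 3488 (all but wild-type replicate 2) and 77 to 335 (every library). MondoA gave 59 to 267 (every library) and 131 to 387 (all but knockdown replicate 2), and MLX 9 to 35 (knockdown replicate 1) and 0 to 1 (knockdown replicate 2). With fewer lists a region has fewer conditions to meet, which by itself raises these counts. H3K4me3 regions of changed length numbered 0 to 165 (every library), and lists with gained or lost peaks 0 to 1 (wild-type replicate 1). The MondoA ratio of peak numbers ran from 0.689 to 1.04 and reversed to 1.04 without knockdown replicate 2 and 1.02 without wild-type replicate 2. The H3K9ac ratio stayed at 1.19 to 1.26 and the MLX ratio at 1.43 to 2.53. Of these values 31 stayed close, 27 moved and 2 reversed. Holding lists to the same number of peaks gave 226 H3K4me3 regions only in knockdown and 174 only in wild type, 373 and 263 for H3K9ac, 61 only in wild type for MondoA, and 1 and 2 for MLX. Equal numbers remove the excess of knockdown peaks by construction, and 9 of these 16 values stayed close. The replicate block ended all 42 H3K4me3 length calls (0, lowest adjusted p 0.071, 2080 at an unadjusted p under 0.05 by limma). The replicates share only a number, since the deviations correlated at −0.00316 for H3K4me3 and −0.0317 for H3K9ac, and the block leaves 1 residual degree of freedom fewer. All 20 values at a −log10 q of at least 5, all 12 with 50% of the region covered and all 4 with the 2.5 kb window stayed close. Over all alternatives other than a left-out library, 58 values stayed close, 8 moved and 1 reversed. That was the odds ratio of H3K9ac gains at H3K4me3 gains, 0.521 among genes with a peak in knockdown and none in wild type, a background chosen after seeing the data. Requiring a peak there leaves out most genes that gained neither mark (187 stay, against 6913 without this requirement), which by itself lowers the ratio. Unless stated, the cause was not tested. The search for the E-box motif and its 4 alternatives was not run, since it needs a genome sequence. The lists give relative depth only, so what depth limits could not be stated beyond the 23 to 62 peaks of the MLX lists.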

Other observations

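The tests that weigh explanations and the test of MLX-bound regions below were chosen only after the results they concern were seen.

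At 12 sites, most of them named above, every MondoA and every MLX list had a peak in the same merged region. The others, with the names here chosen after their values were seen, included COQ8A, a gene of coenzyme Q synthesis, AKAP10, a gene of protein kinase A anchoring, YTHDF2, which encodes a reader of modified RNA, and DHRS2, a dehydrogenase gene. From knockdown replicate 1 to 2 the authors' MondoA fold rose from 16.7 to 67.8 at YTHDF2 and from 50.8 to 115 at DHRS2. It also rose at PGK1 (91.3 to 366) and fell at TXNIP (206 to 158). Whether plasmid reads, in doubt at PGK1, also lie at YTHDF2 and DHRS2 was not tested. In wild type the MondoA and MLX peaks at COQ8A shared no base, and at AKAP10 that of MondoA replicate 1 shared none with those of MLX. The authors' MLX fold at COQ8A was 31.9 and 63.0 in knockdown and 15.4 and 21.1 in wild type. The 63.0 came from knockdown replicate 2, whose MLX fold was also above that of replicate 1 at TXNIP and ARRDC4. Other sites were called for MLX in every list and lay in no MondoA region called in both libraries of a cell type. One was PPP1R3B, which encodes a subunit that brings a phosphatase to glycogen, with folds of 18.0 and 33.0 in knockdown and 16.7 and 11.8 in wild type. Others lay at DIAPH1 and SLC60A2.

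Most regions gained by H3K4me3 carried H3K9ac in some list. Of the 781 H3K4me3 regions called only in knockdown, 538 (68.9%) overlapped an H3K9ac peak in any list and 110 (14.1%) an H3K9ac region called in all lists. The same shares were not computed for H3K4me3 regions called in all lists, so these values are not shown to be particular to the gained set. Of the 1660 H3K9ac regions called only in knockdown, 459 (27.7%) overlapped an H3K4me3 region called in all lists.

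More H3K4me3 and H3K9ac regions were called in knockdown. The background floors argued against a difference in fragment number as the whole cause, since they gave a difference of −0.875 H3K4me3 peaks against 1376.5 seen, and of at most 784 H3K9ac peaks against 3501 seen, where the SDs of the groups add to 1168. Extra copies of a few chromosomes were also argued against as the only source, since all 23 chromosomes had more regions only in knockdown for both marks. A smaller part for copy number was not tested. Relative to regions called in all lists, those only in knockdown ran from 3.97% (chromosome 16) to 8.46% (chromosome 21) for H3K4me3. For H3K9ac they ran from 6.59% (chromosome 14) to 16.1% (chromosome 10). Weak sites that cross the caller's threshold stay a candidate explanation. For H3K4me3, 97.95% and 98.5% of the peaks in these regions lay in the weakest 20% of the knockdown lists, and for H3K9ac 63.1% and 71.5%. These regions were chosen for having no wild-type peak, so they would tend to be weak after a true gain as well. The shares therefore decide nothing for either mark. The H3K4me3 summit pileup over the floor in shared regions was 1.34 times that of wild type. A better yield of the immunoprecipitation, a response to PKM depletion and a response to the vector or hairpin cannot be told apart here. Yield follows the cells, no spike-in scale was used and no cells with a control vector are labelled.

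The H3K4me3 and H3K9ac regions at TXNIP were longer in knockdown. For extra copies of the locus, the background within 1 Mb relative to all peaks was 0.840 ± 0.0418 times that of wild type in the histone lists (SD, n = 2 replicates with the marks averaged, 22 to 32 peaks per list), where a gain from 3 copies to 4 would give 1.33. The MondoA lists gave the other direction, 1.13, from 1 or 2 peaks each. At TXNIP itself the mean background of the MondoA and MLX lists was 1.78 times the floor in knockdown and 1.67 in wild type. The H3K4me3 knockdown medians within 1 Mb were at or near the floor (1.00 and 1.05 times). Such a background follows copy number only if an input was the control, which is not given, so extra copies were left undecided. A general gain in length was argued against as the whole cause, since after the shift of the library medians was removed the log2 changes were 0.68 (SE 0.054) for H3K4me3 and 0.73 (SE 0.106) for H3K9ac, both past the test adjusted over the target list alone, although the latter did not pass over all regions and 0.847% and 2.22% of shared regions gained as much. A response of this locus to PKM depletion is a hypothesis that stays open. Without a control hairpin it cannot be told apart from a response to the vector.

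MondoA and MLX peaks at PGK1 and at a site beside RNU6-1, a U6 small nuclear RNA gene on chromosome 15 (67839939 to 67840045), had fixed edges. Reads of the hairpin vector, pLKO.1-puro per the labels, which is known to carry human U6 and PGK promoters, in knockdown cells alone were argued against, since the edges varied by at most 8 bp over the 4 wild-type lists, against at least 43 bp at the other 10 sites. Reads of plasmid copies of both promoters in the second batch are a candidate explanation, since the edges varied by at most 14 bp over the 8 lists, against at least 46 bp at the other 10 sites (median 242.5). The mean local background in that batch, which the lists of a cell type may share through 1 input, was 12.6 times the floor in wild type and 2.13 in knockdown at PGK1, 5.28 and 2.53 beside RNU6-1, and at most 2.01 in wild type at the other sites. In the histone lists of the first batch it was instead higher in knockdown, at 1.8 to 1.99 against 1.41 to 1.53 beside RNU6-1 and 1.45 to 1.46 against 1.37 to 1.38 at PGK1. The H3K4me3 background over all peaks was also higher in knockdown (1.47 and 1.51 against 1.43 and 1.42). That of H3K9ac overlapped between the cells (1.475 and 1.471 against 1.461 and 1.494). The smallest edge ranges of the other 10 sites, 43 and 46 bp, were both at DHRS2. Its MondoA fold rose between the knockdown replicates as at PGK1, so it may not be a clean comparison. The median range at the 10 sites over the wild-type lists was 155.5 bp. The wild-type background was 1.26 times the floor at DHRS2 and 1.21 at YTHDF2. No biological explanation was tested.

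One hypothesis was that regions bound by MLX gained length against regions of like length. The 15 H3K4me3 regions with MLX in all lists had a median log2 change of 0.06, with 11 above the library median, against −0.02 (−0.08 to 0.04) in 10000 random sets (two-sided permutation p = 0.0086, adjusted p = 0.0258 over 4 tests). Without TXNIP, an alternative chosen like the next after seeing the data, the median was 0.06 over 14 regions (permutation p = 0.0121), and without the regions at PGK1 and beside RNU6-1, where plasmid reads are in doubt, it was 0.06 over 13 (permutation p = 0.022). For the 16 H3K9ac regions the median was also 0.06 (permutation p = 0.211, adjusted p = 0.281), which leaves that mark open. MondoA regions gave −0.04 for H3K4me3 (permutation p = 0.838) and −0.05 against a random −0.07 for H3K9ac (permutation p = 0.0129, adjusted p = 0.0258). The H3K4me3 result is consistent with a small gain at MLX-bound sites, found and tested on the same data.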
